A study of Mus musculus with 44 samples.

How the data were processed

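Microglia, the resident immune cells of the brain, were sorted by FACS for CD11b and CD45 from brains of female and male mice aged 8 months, per the series design text. Per the labels' protocols, poly(A) RNA was isolated, cDNA was made with a low-input SMART-Seq kit and libraries were prepared with Nextera XT; this chemistry does not mark the strand, so reads of a gene and of an antisense partner cannot be told apart. Alignment to the mouse genome mm9 with STAR is given by the design text, and the submitters' processing notes name STAR, HTSeq and edgeR without versions. The values analysed here were RPKM (reads per kilobase of gene length, scaled to library size) per gene, deposited by the authors in 1 table for 27 female and 1 table for 17 male libraries, with 37583 genes each. How each tool was used is not given in the sources used here. Every column was matched to its sample by the number and genotype in its name. The RPKM of each table had been scaled separately, so tests between genotypes were run within a table, and the sexes were compared only through differences of genotype effects. Of the gene names, 25 had been turned into dates by spreadsheet software and were restored from the gene identifiers, and 37168 identifiers (98.9%) were in the mm9 annotation used for coordinates. The gene length given in the tables equalled the merged exon length less 1 base per merged exon for 69.8% of these identifiers.

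The number behind each value was recovered from the deposited RPKM: multiplied by gene length and by the value of 1 read, 100.0% of the values of each library were whole reads within a tolerance of 0.01 reads. Libraries held 5.89 to 42.4 M reads assigned to genes, and the authors' scaling factors ranged from 0.80 to 1.26. Depth fell into separate ranges, 10 deep libraries with 26.5 to 42.4 M reads and 34 shallow libraries with 5.89 to 16 M reads. The sets followed the library numbers without overlap: deep females were numbered 25 to 34 and shallow ones 1 to 24, deep males 21 to 24 and shallow ones 1 to 15. No label names a batch, and each of the 7 genotype and sex groups held 1 or 2 deep libraries. Library pairs within a group differed by far more than sampling noise (lowest chi-square per degree of freedom 6.8 to 30.5 between groups), so none was counted as a duplicate. The labels number each library, and each number was read as 1 mouse; the labels do not say outright that the numbers are mice, so the p-values measure the spread between these libraries.

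Choices of groups, tests, gene lists, named genes and alternatives were made before the data were examined, apart from the added alternatives named below. Genes with at least 1 RPKM in at least 5 libraries of a table were kept, values were taken as log2(RPKM + 1) with a pseudocount of 1, and limma 3.58.1 in R 4.3.3 was fitted with the trend and robust options of its empirical Bayes step. Comparisons within a sex used 1 mean per genotype group over all libraries of that sex, trends used the number of T96K alleles over the 5xFAD libraries of a sex, and sex differences used the libraries of both sexes in 1 fit. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes with low values. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called. The comparisons were 5xFAD Trem2+/+, T96K/+ and T96K/T96K against NonTg in females, the T96K genotypes against Trem2+/+ 5xFAD and against each other in each sex, a trend per T96K allele, and the difference of each T96K effect between the sexes, in which a positive value is an effect that was higher in females than in males. The named genes were Trem2, Tyrobp, Apoe, Cst7, Clec7a, Itgax, Lpl, Spp1, Gpnmb, P2ry12, Tmem119 and Cx3cr1, then the 8 called genes with the largest rise and the 8 with the largest fall among those with a group mean of at least 2 RPKM (predicted and non-coding models left out), then the 4 members with the smallest p of each list past the list test; with fewer than 5 genes called, the 5 with the smallest p were named as not called. Xist, Ddx3y and Uty served as a check of the sex labels.

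A total of 32 gene lists, 19 of pathways and 13 of cell type markers, were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were run beside it. The T or NK cell list had too few tested genes in either sex, and the oligodendrocyte precursor list too few in males. Scores were the mean log2(RPKM + 1) over the DAM stage 2, homeostatic and type I interferon lists in each library, compared by exact two-sided permutation tests adjusted over 27 tests; DAM stands for disease-associated microglia. The gene-wise fit was tested on simulated data in which known genes were changed by 1.5, 2 or 4-fold. Each gene was drawn independently there, so the rates below leave out variation that many genes of a library share. For 5xFAD Trem2+/+ against NonTg it recovered 17.7, 45 and 80.3% of them over 14397 genes; for female T96K/+ against +/+ 32.8, 46.9 and 78.8% over 14527 genes; for male T96K/+ against +/+ 44.4, 64.5 and 93.8% over 13659 genes; false calls made up 4.2, 6.4 and 7.9% of the calls in turn.

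Also chosen beforehand were a pseudocount of 0.1, no filter on low values, quantile normalization, scaling of each library to the same median, array weights, only the compared groups in the fit, and leaving out each library in turn. Alternatives added after seeing the data were the depth set as a covariate, shallow libraries only, leaving out the 2 deep NonTg libraries, the endothelial, oligodendrocyte and neutrophil marker scores as covariates, and limma voom on the recovered reads with a prior of 0.5 reads. Splits of the libraries into groups of the same sizes, 100 per comparison with the real one among them, were compared. Tables were prepared with Python 3.11.15 and pandas 2.3.3 and plotted with matplotlib 3.10.9.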

Results

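The libraries came from microglia of NonTg mice and of 5xFAD mice, a transgenic line that expresses mutant human amyloid precursor protein and presenilin and forms amyloid plaques. The 5xFAD mice carried 0, 1 or 2 copies of the T96K allele of Trem2, which encodes a lipid-sensing receptor of microglia. Trem2 (ENSMUSG00000023992) lies on chromosome 17 at 48485726 to 48493472 of mm9, on the + strand, and codon 96, threonine in the reference, lies in exon 2 of 5 at 48488027 to 48488029. There were 27 female libraries (5 NonTg, 6 5xFAD Trem2+/+, 9 5xFAD T96K/+ and 7 5xFAD T96K/T96K) and 17 male libraries, all 5xFAD (5 Trem2+/+, 6 T96K/+ and 6 T96K/T96K); NonTg males were not analysed here. Median depth (M reads) was 16 in NonTg, 12, 11.7 and 11.8 in female Trem2+/+, T96K/+ and T96K/T96K, and 7.15, 8.18 and 10.3 in the male groups in the same order. The series asks how T96K, which its title calls a gain-of-function mutation, changes microglia in an amyloid model.

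Trem2 stood at 289 ± 172 RPKM in NonTg females (SD, n = 5) and at 1069 ± 422 (n = 6), 913 ± 229 (n = 9) and 962 ± 264 (n = 7) in female 5xFAD Trem2+/+, T96K/+ and T96K/T96K microglia. In males it stood at 920 ± 108 (n = 5), 746 ± 111 (n = 6) and 826 ± 171 (n = 6). RPKM per gene carries no allele information, so the Trem2 genotypes were taken from the labels. Xist, the RNA of the inactive X chromosome, and the sum of 4 Y-linked genes matched the sex label in all but 1 library. The library labelled female T96K/+ 22 held 0.416 RPKM of Xist against at least 16.9 in the other 26 female libraries, and 29.3 RPKM of the Y-linked genes against 25.7 to 37.9 in males. It was kept under its label, and counts without it are given below.

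**Figure D1:**
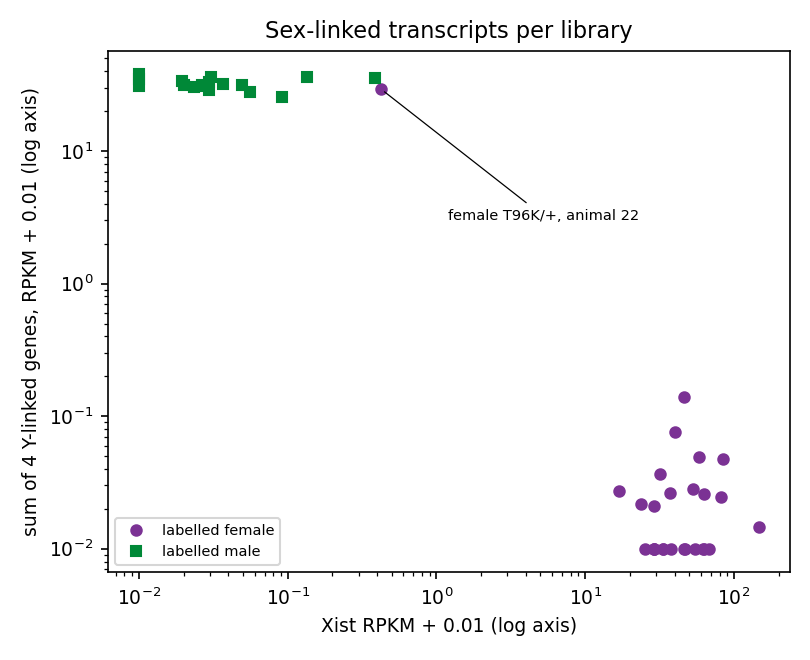
Xist against the sum of 4 Y-linked genes in each library, in RPKM on log axes with 0.01 added, coloured by the sex on the label. The library labelled female T96K/+ 22 (Xist 0.416, Y-linked sum 29.3) sits with the 17 male libraries, away from the other 26 female libraries.

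The first comparison asked what the 5xFAD background did to female microglia with normal Trem2. Genes of the disease-associated state rose steeply in 5xFAD Trem2+/+ (n = 6) over NonTg (n = 5). Cst7, a cysteine protease inhibitor, rose by 7.74 on the log2 scale (SE 0.75), from 16.3 ± 21.1 to 1843 ± 1461 RPKM (SD). Its NonTg values were 0.738 to 1.17 RPKM in the shallow libraries, but 43.0 and 35.5 in the deep libraries 28 and 30. Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 6.41 (SE 0.52), Spp1, which encodes osteopontin, by 5.76 (SE 0.72), and Igf1, a growth factor, by 5.16 (SE 0.35, adjusted p = 4.03e-10 by limma). Trem2 itself rose by 2.0 (SE 0.30, adjusted p = 2.66e-05), a 3.99-fold change, and its signalling adaptor Tyrobp by 2.55 (SE 0.40, adjusted p = 4.85e-05). NonTg values of Trem2 were 147.7 to 198.2 RPKM in the shallow libraries and 539.1 and 397.5 in the deep libraries 28 and 30. Trem2+/+ 5xFAD libraries held 609.2 to 1831, so all lay above NonTg, but the size of the rise depended on which NonTg libraries were used. The homeostatic genes P2ry12 (0.40, SE 0.34), Tmem119 (-0.57, SE 0.41) and Cx3cr1 (0.54, SE 0.35) did not pass the test, nor did the lipid carrier Apoe (1.75, SE 0.90, adjusted p = 0.17), whose RPKM in 5xFAD Trem2+/+ was 4060 ± 5745. Apoe stood at 761.6 to 1387 RPKM in Trem2+/+ libraries 1 to 14, but at 15220 and 5330 in libraries 19 and 25.

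Clec7a, a receptor for fungal glucans, rose by 5.22, the integrin Itgax by 4.67 and lipoprotein lipase Lpl by 4.66. The other genes with the largest rises were Cox6a2 (5.79), Fabp5 (4.81) and Mamdc2 (4.78). The largest falls were in Cyr61 (-2.61, SE 0.62), the B cell scaffold gene Bank1 (-2.48, SE 0.38), Gpr37l1 (-2.34), the endothelial gene Ecscr (-2.13), Car4 (-2.04), the gap junction gene Gja1 (-1.98), Grap (-1.96) and the transporter Slc22a8 (-1.96). Gja1 is on the astrocyte marker list, and endothelial markers fell as well (below). These falls were not separated from a smaller share of RNA of other cells, so they need not be changes in microglia. In mm9, Cst7 lies on chromosome 2 at 150396151 to 150404680, Gpnmb on chromosome 6 at 48986517 to 49020928, Igf1 on chromosome 10 at 87321010 to 87399792 and Bank1 on chromosome 3 at 135716327 to 135989030.

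All 11 tested genes of DAM stage 2 rose (median 3.51), 11 also when adjusted over the list alone, as did 19 of 20 plaque-associated genes (median 3.59; 19 adjusted over the list alone), among them Dkk2 (4.10). Of 18 genes of lipid handling, 10 rose and 2 fell (11 and 2 adjusted over the list alone), with Fabp3 at 3.85 and the cholesterol acyltransferase Soat1 at 1.82. These 3 lists passed camera with both a preset and an estimated correlation (adjusted p = 0.0483 with an estimated correlation for each). They overlap, so they are not separate results: lipid handling holds Fabp5, Fabp3 and Ch25h of the plaque-associated list and Lpl of DAM stage 2. Of 7 genes of DAM stage 1, 5 rose (6 adjusted over the list alone), including the proteases Ctsb (2.26) and Ctsd (2.17) and B2m (1.84); adjusted p = 0.189 with an estimated correlation.

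The lysosome list had 24 of 29 genes higher (24 adjusted over the list alone), such as Lamp2 (1.31), Ctsl (2.19) and Gusb (1.87); adjusted p = 0.157 with an estimated correlation. Of 27 type I interferon genes 13 rose (14 adjusted over the list alone), led by Ifi27l2a (4.18) and Ifi204 (2.60), of 12 MHC class I genes 7 (9 alone), including Nlrc5 (1.59), and of 11 complement genes 7 (8 alone), including C3ar1 (1.54) and C1qa (1.53); adjusted p = 0.189 with an estimated correlation for each of the 3. Of 20 inflammatory genes 8 rose (8 alone), such as Tlr2 (2.20) and Cxcl16 (1.53), and of 15 glycolysis genes 10 rose and 1 fell (10 and 2 alone), such as the lactate exporter Slc16a3 (2.24) and Gapdh (1.35); adjusted p = 0.296 with an estimated correlation for both. Of 20 proliferation genes 11 rose (11 alone), with Cdk1 at 1.58; adjusted p = 0.253 with an estimated correlation. With marker scores as covariates, 2 glycolysis and 2 proliferation genes were called, and quantile normalization gave 4 complement genes higher and 1 lower (median 0.20).

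All 44 cytosolic ribosomal protein genes rose (44 adjusted over the list alone), by a median of 1.59, with Rps28 at 2.49 and Rpl32 at 2.29; adjusted p = 0.189 with an estimated correlation. With marker scores as covariates 3 of the 44 stayed called. Of 31 genes of oxidative phosphorylation 10 rose and 0 fell (13 adjusted over the list alone; median 0.27), such as Ndufa1 (2.18); adjusted p = 0.596 with an estimated correlation. Under quantile normalization that list turned to 2 higher and 7 lower, and with marker scores as covariates 0 genes stayed called (median 0.16). Of 21 immediate early genes 1 rose, Egr2 (1.33), and 3 fell, Klf2 (-1.71) and the heat shock genes Hspa1a (-1.64) and Hspa1b (-1.73), with counts of 1 and 3 adjusted over the list alone and adjusted p = 0.596 with an estimated correlation. Quantile normalization gave 1 higher and 12 lower in that list (median -1.29).

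Lists that did not pass camera were the homeostatic list (1 of 24 higher and 3 lower, adjusted p = 0.767), MHC class II (4 of 9 higher, 0.0878), cholesterol biosynthesis (5 of 19 higher and 1 lower, 0.0683), TREM2 signalling (4 of 15 higher, 0.059) and Alzheimer disease risk genes (3 of 22 higher and 3 lower, 0.329), with the numbers in brackets being adjusted p-values. Adjusted over the list alone, the counts were 1 and 3, 4, 5 and 1, 4, and 7 and 3. In the homeostatic list the median change was 0.22 and the mean 0.08, and its direction depended on the setting. Quantile normalization gave 0 higher and 7 lower (median -0.43), and shallow libraries alone 10 higher and 3 lower (median 0.68). With 5xFAD genotypes pooled and no test run, all its genes but Mef2c had lower mean RPKM in deep 5xFAD than deep NonTg libraries. P2ry12 stood at 234 against 507 and Csf1r at 795 against 1342. Among shallow libraries these genes stood higher in 5xFAD, at 391 against 201 and 1299 against 559, while Crybb1, Gpr56, Serinc3 and Txnip were lower. The values over all libraries averaged over these differences.

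Markers of vascular cells moved the other way in the same libraries. Of 8 endothelial genes 7 fell (7 adjusted over the list alone; median -1.31), such as Pecam1 (-1.60), Kdr (-1.42), Cldn5 (-1.36) and Cdh5 (-1.27); adjusted p = 0.214 with an estimated correlation. Of 5 mural cell genes 3 fell (5 alone; median -1.23), such as Vtn (-1.59) and Kcnj8 (-1.54); adjusted p = 0.215 with an estimated correlation. Of 10 oligodendrocyte genes 1 fell, Mal (-0.81), with a list median of -0.45; adjusted p = 0.253 with an estimated correlation. The mean endothelial level was 6.42 ± 0.54 in NonTg and 5.21 ± 0.39 in 5xFAD Trem2+/+ (SD, log2). Camera did not call astrocyte (1 of 9 higher and 4 lower, adjusted p = 0.0567), oligodendrocyte precursor (1 of 3 lower, 0.107), border-associated macrophage (1 of 10 higher and 1 lower, 0.177) or monocyte genes (1 of 7 lower beside a median of 1.29, 0.372). The neuron, neutrophil, B cell, erythroid and choroid plexus lists had 0 genes called, and camera gave adjusted p-values of 0.602, 0.186, 0.456, 0.602 and 0.602.

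In all, 3438 of 14591 genes were called, 1972 higher and 1466 lower (57.4% higher), and 1286 of them by at least 2-fold (797 higher, 489 lower). Quantile normalization called 1524 higher and 1807 lower (45.8% higher), with 2956 genes shared. Of 31 lists, camera called 17 (13 higher, 4 lower), camera with an estimated correlation 3 and fry 18. With the endothelial, oligodendrocyte and neutrophil marker scores as covariates, 578 genes were called.

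**Figure D2:**
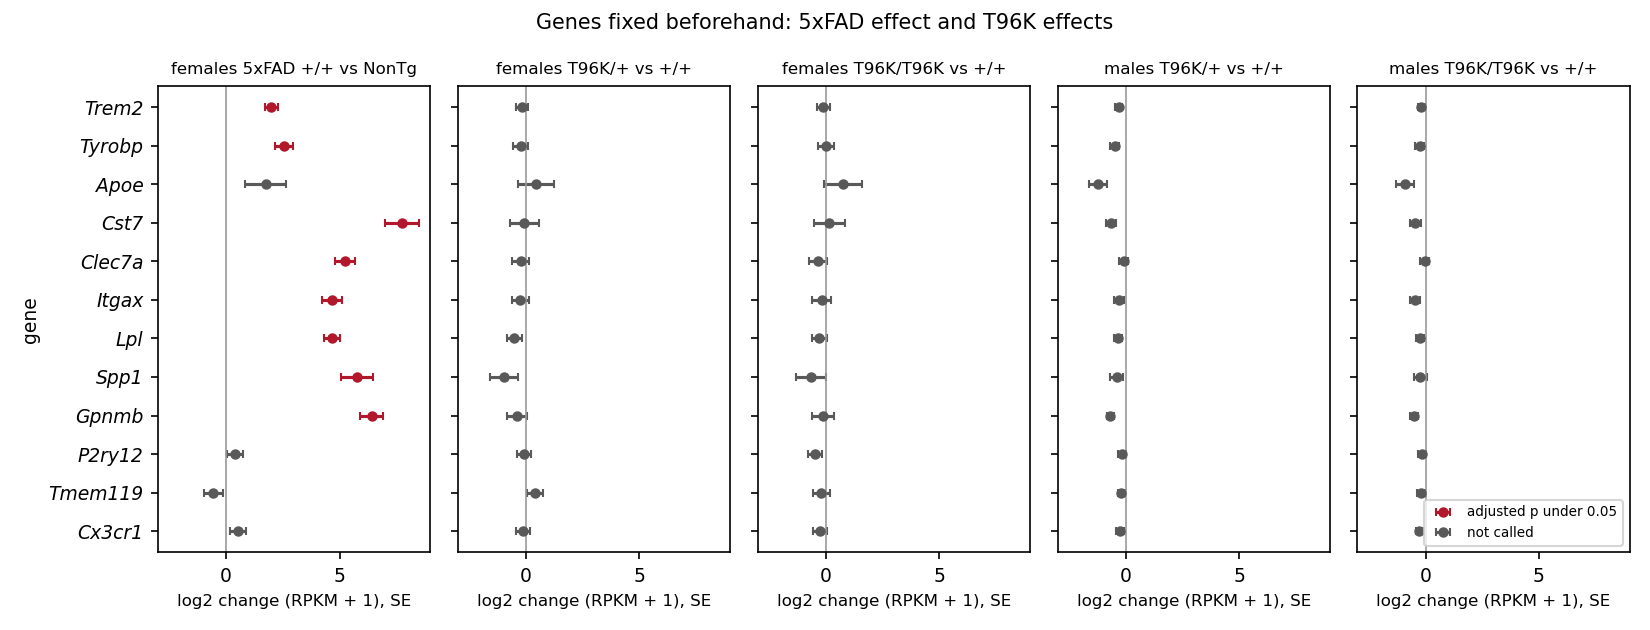
Change on the log2(RPKM + 1) scale, with bars of 1 SE, of the 12 genes chosen beforehand, in the 5xFAD Trem2+/+ against NonTg comparison and in 4 T96K comparisons within 5xFAD; red marks an adjusted p under 0.05. Cst7 reached 7.74 and Gpnmb 6.41 in the first panel, and none of the 12 genes was called in the T96K panels.

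The T96K genotypes of 5xFAD females were next set against NonTg. Cst7 rose by 7.67 (SE 0.69) in T96K/+ (n = 9) and by 7.88 (SE 0.73) in T96K/T96K (n = 7), Gpnmb by 6.01 and 6.28, Spp1 by 4.78 and 5.09, Trem2 by 1.82 and 1.89 and Tyrobp by 2.31 and 2.55. Igf1 rose by 4.72 and 5.03, and Cox6a2 by 5.31 and 5.62. Apoe stayed short of the threshold at 2.18 (adjusted p = 0.0718 by limma) and 2.49 (0.0524). Bank1 fell by 1.92 and 2.08 and Cyr61 by 2.26 and 1.84. The largest falls otherwise were in Rarres2 (-1.98), Tmem212 (-1.84) and Nr4a1 (-1.75) in T96K/+, and in Gpr37l1 (-2.11), Mlc1 (-1.88) and Gja1 (-1.84) in T96K/T96K. Tmem212 is on the choroid plexus or ependymal marker list and Gja1 on the astrocyte list, so RNA of other cells was not separated from these falls.

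DAM stage 2 had 11 of 11 genes higher in both genotypes (11 and 11 adjusted over the list alone), the plaque-associated list 19 and 18 of 20 (19 and 19 alone), and lipid handling 9 higher with 2 lower, and 10 higher with 1 lower (10 with 2, and 11 with 2 alone). These 3 lists kept their call with an estimated correlation (adjusted p = 0.0297 and 0.0271). Ribosomal protein genes were higher for 43 and 44 of 44 (44 and 44 alone; 2 and 40 with marker scores as covariates; adjusted p = 0.166 and 0.123 with an estimated correlation), lysosome genes for 25 and 23 of 29 (27 and 25 alone, with 1 and 0 lower; 0.0746 and 0.0893) and interferon genes for 13 and 16 of 27 (16 and 18 alone; 0.113 and 0.0893). Beside these, 5 and 1 of 8 endothelial genes were lower (8 and 1 alone; median -0.95 and -0.55; adjusted p = 0.236 and 0.469 with an estimated correlation), and 2 and 3 of 10 oligodendrocyte genes (3 and 6 alone; 0.26 and 0.0893). Camera called 19 of 31 lists in each genotype (14 higher, 5 lower), camera with an estimated correlation 3 in each, and fry 19 and 15.

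T96K/+ differed from NonTg in 2530 genes (1498 higher, 1032 lower, 59.2% higher) and T96K/T96K in 2236 (1499 higher, 737 lower, 67% higher); quantile normalization gave 1238 and 1392 (47.1% higher) and 1258 and 1379 (47.7% higher). Of the 3902 genes called in any comparison with NonTg, 1189 were higher and 474 lower in all 3. Without NonTg library 4 the counts were 1547 and 1425, without NonTg library 24 that for T96K/+ was 1549, and with marker scores as covariates they were 644 and 1055. Without the library labelled female T96K/+ 22, T96K/+ differed from NonTg in 2583 genes. Across genes, which are not independent replicates, the changes correlated at r = 0.929 between Trem2+/+ and T96K/+, 0.927 between Trem2+/+ and T96K/T96K and 0.912 between the T96K genotypes. Unchanged groups simulated against the shared NonTg libraries, with each gene drawn independently, gave 0.593, 0.561 and 0.613. Separate NonTg libraries for each comparison gave 0.708, 0.716 and 0.673. The covariances were 0.318, 0.335 and 0.282 against 0.041, 0.040 and 0.041 in the simulation. Trem2+/+ and T96K/+ shared 1365 higher and 896 lower genes, where independent lists of those sizes would share 202.5 and 103.7; for Trem2+/+ and T96K/T96K the counts were 1372 and 609 against 202.6 and 74, and for the T96K genotypes 1222 and 501 against 153.9 and 52.1. These lists were not independent, as they used the same NonTg libraries. That alone raises the overlap, so the expected counts are too low and do not serve as a test.

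The central question was whether T96K altered the 5xFAD response in females. Against 5xFAD Trem2+/+, no disease-associated gene of T96K/+ microglia passed the test: Cst7 differed by -0.07 (SE 0.66), Gpnmb by -0.39 (SE 0.45), Spp1 by -0.98 (SE 0.62), Lpl by -0.51 (SE 0.31), Clec7a by -0.24 (SE 0.39) and Trem2 by -0.18 (SE 0.26). In T96K/T96K, Cst7 differed by 0.15 (SE 0.69), Gpnmb by -0.13 (SE 0.48), Spp1 by -0.66 (SE 0.66), Trem2 by -0.11 (SE 0.27) and P2ry12 by -0.47 (SE 0.32). The genes with the smallest p, none of them called, were Npy (1.49, SE 0.33), Gm10973 (-1.58), Emr4 (-0.82), U6 (-1.35) and 4933406P04Rik (0.65) in T96K/+, and Gm10973 (-1.64), Gm11399 (1.2), Snora69 (-1.0), Gm6420 (-0.84) and 4930412M03Rik (-0.78) in T96K/T96K. Npy, which encodes a neuropeptide, stood at 1.2 ± 1.35 RPKM in Trem2+/+, 4.79 ± 2.12 in T96K/+, 2.21 ± 1.1 in T96K/T96K and 5.22 ± 2.32 in NonTg (SD).

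By list, camera placed 13 of 31 apart in T96K/+ (3 higher, 10 lower). Plaque-associated genes stood at a median of -0.38 (0 genes called over all genes or over the list alone; adjusted p = 0.577 with an estimated correlation), with Lgals3 at -1.10 (SE 0.46), MHC class II genes stood at -0.24 (0.496), with H2-Aa at -0.95, and ribosomal genes at -0.20 (0.801). Markers of blood cells lay lower too. The monocyte list stood at -1.59 (0 of 7 genes lower over all genes and 5 adjusted over the list alone, among them Plac8 at -2.06 and the chemokine receptor Ccr2 at -0.89), the neutrophil list at -0.97 and the erythroid list at -1.33, with adjusted p = 0.164, 0.546 and 0.375 with an estimated correlation. The immediate early list stood at 0.27, with Egr1 at 0.95 and Fosb at 1.18, and the endothelial list at 0.31 (0.692 and 0.732). In T96K/T96K camera placed 5 lists apart, with endothelial genes at 0.63 (1 of 8 adjusted over the list alone, Cdh5 at 0.83), mural genes at 0.69, neutrophil genes at 0.93, inflammatory genes at -0.21 and oxidative phosphorylation at -0.11 (adjusted p = 0.624, 0.624, 0.93, 0.93 and 0.93 with an estimated correlation).

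Between T96K/T96K and T96K/+ females, 0 genes were called, and camera at the preset correlation placed 10 lists apart. The neutrophil list stood higher in T96K/T96K by a median of 1.98 (9 of 10 genes adjusted over the list alone, 0 over all genes), with the granule genes Ngp at 2.31 and Camp at 2.08, and the monocyte list by 1.78 (6 of 7 alone), with Ly6c2 at 2.39 (adjusted p = 0.146 and 0.0738 with an estimated correlation). MHC class II genes stood at 0.49, with H2-Ab1 at 0.90 and Cd74 at 1.05, homeostatic genes at -0.16, oligodendrocyte genes at -0.26 and endothelial genes at 0.41 (0.494, 0.794, 0.221 and 0.669). The genes with the smallest p, not called, were B930036N10Rik (-0.74), 1500002C15Rik (-0.83), Zfp788 (-0.44), the neutrophil gene Cd177 (1.68) and U5 (-1.58). Along the trend per allele, 5 lists passed camera, with Cdh5 at 0.42 and Vtn at 0.35 per allele; the endothelial list stood at 0.31 and the mural list at 0.35 (adjusted p = 0.431 with an estimated correlation for both).

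Among 14591 genes limma called 0 in T96K/+, T96K/T96K, their contrast and the trend, beside 523, 544, 514 and 681 genes at an unadjusted p under 0.05, and limma voom also called 0 in each. Camera with an estimated correlation and fry called 0 lists in all 4 (smallest adjusted p by fry 0.235, 0.795, 0.0786 and 0.436). Without the library labelled female T96K/+ 22 the counts of T96K/+, the contrast and the trend were 0 as well. The T96K/+ count was 1 without Trem2+/+ library 13 (U6) or 14 (Gm10973, also the 1 gene called in T96K/T96K without it). The correlation of both T96K effects across genes was 0.512, beside 0.57 for unchanged groups sharing the Trem2+/+ libraries and -0.052 with separate Trem2+/+ libraries for each; the covariance was 0.029 against 0.034.

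The same genotypes were compared in male 5xFAD microglia. In T96K/+ (n = 6) against Trem2+/+ (n = 5), Apoe stood at -1.22 (SE 0.41), from 4447 ± 2687 to 1643 ± 383 RPKM (SD), Gpnmb at -0.67 (SE 0.17), Cst7 at -0.65 (SE 0.24), Tyrobp at -0.48 (SE 0.20) and Trem2 at -0.31 (SE 0.15), none of which passed adjustment (adjusted p = 0.307, 0.237, 0.33, 0.366 and 0.425 by limma). The smallest p-values, also not called, belonged to Ccdc134 (-0.54), Gnpda2 (0.36), Spns1 (-0.32), Leprel1 (-0.50) and the interferon-induced Mx1 (-0.84, SE 0.17), each with adjusted p = 0.159. Mx1 stood at 2.66 ± 0.43 RPKM in Trem2+/+ and 1.07 ± 0.42 in T96K/+ (SD).

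Camera placed 22 of 30 lists apart in male T96K/+, 16 lower and 6 higher. Lower were lysosome genes (median -0.30), with Ctss at -0.50, DAM stage 1 (-0.43; 2 of 7 lower adjusted over the list alone, with Lyz2 at -1.01), DAM stage 2 (-0.32), plaque-associated genes (-0.28; 2 of 20 alone, Gpnmb and Dkk2 at -0.38), homeostatic genes (-0.18), with Csf1r at -0.38, interferon genes (-0.19; 1 of 27 alone), complement (-0.31), TREM2 signalling (-0.31; 1 of 15 alone, the kinase Syk at -0.47) and Alzheimer disease risk genes (-0.28). Lower also were border-associated macrophage genes (-0.30; 1 of 9 alone) and neutrophil genes (-0.87; 7 of 10 alone), with Lcn2 at -1.03. Higher were oxidative phosphorylation (0.16) and, beside it, the astrocyte (0.54), oligodendrocyte (0.49), endothelial (0.48) and mural (0.55) marker lists. None of these lists kept its call; adjusted p = 0.47 or 0.475 with an estimated correlation for each.

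Male T96K/T96K microglia (n = 6) showed Dkk2 at -0.57 (SE 0.10) and Leprel1 at -0.57, each with adjusted p = 0.136 by limma, then Ift172 (-0.42), Fdps (0.45), an enzyme of isoprenoid synthesis, and Idua (-0.47). Apoe stood at -0.91 (SE 0.41), Gpnmb at -0.49 (SE 0.17) and Trem2 at -0.18 (SE 0.15). Camera placed 17 lists apart, 11 lower and 6 higher. Border-associated macrophage genes lay at -0.46 (5 of 9 lower adjusted over the list alone, with F13a1 at -0.89 and Pf4 at -0.70; adjusted p = 0.294 with an estimated correlation). Oxidative phosphorylation lay at 0.20, cholesterol biosynthesis at 0.12 (2 of 19 higher alone, Fdps and Sqle at 0.30), ribosomal genes at 0.17 and oligodendrocyte genes at 0.43, and lysosome genes at -0.18 (0.383, 0.578, 0.578, 0.383 and 0.578). Against T96K/+, the neutrophil list was higher by 0.86 in T96K/T96K (8 of 10 alone, with Lcn2 at 1.0; adjusted p = 0.563 with an estimated correlation), and the smallest p-values belonged to CPEB3_ribozyme (0.87), Gm6467 (0.48), Pmf1 (0.39), Serpinb1a (0.55) and Bik (0.75).

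Among 13845 genes limma and limma voom called 0 in male T96K/+, T96K/T96K, their contrast and the trend per allele, beside 1703, 1193, 342 and 1052 genes at an unadjusted p under 0.05; fry and camera with an estimated correlation called 0 lists. With array weights 62 genes were called in T96K/+ (16 higher, 46 lower), and with only the compared groups in the fit 3 (2310022B05Rik, Svip and Pisd-ps1); without T96K/+ library 22 of the males 1 gene was called (AC161805.1), and 1 in the trend without T96K/T96K library 5 (Gm8974). Both T96K effects correlated across genes at 0.759, beside 0.546 for unchanged groups sharing the Trem2+/+ libraries and 0.287 with separate Trem2+/+ libraries for each. The covariance was 0.053 against 0.028. The simulated genes were independent and no relabelled libraries were compared here, so an effect shared by both genotypes was not tested.

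Scores per library gave a single number for each state. The DAM stage 2 score was 4.61 ± 1.05 in NonTg and 8.29 ± 0.54 in 5xFAD Trem2+/+ females (SD, log2), a difference of 3.68 (95% interval 2.49 to 4.77) with 6 of 6 libraries above all NonTg libraries (adjusted p = 0.0117, exact permutation test). For T96K/+ and T96K/T96K against NonTg it differed by 3.48 and 3.51 (adjusted p = 0.00674 and 0.00852, exact permutation test). T96K/+ differed from Trem2+/+ by -0.20 (-0.78 to 0.39) in females and -0.31 (-0.68 to 0.06) in males, and T96K/T96K by -0.17 (-0.69 to 0.34) and -0.19 (-0.68 to 0.29), so these intervals left out a loss as large as 1 log2 unit in either sex. The interferon score differed from NonTg by 1.0, 0.98 and 1.09 in the female 5xFAD groups (adjusted p = 0.0195, 0.00674 and 0.00852, exact permutation test), and the homeostatic score by 0.08 (-0.60 to 0.75), 0.17 (-0.29 to 0.63) and -0.02 (-0.62 to 0.56). In the males, T96K/+ differed from Trem2+/+ by -0.19 (-0.41 to 0.02) in the homeostatic and -0.21 (-0.45 to 0.03) in the interferon score (adjusted p = 0.26 for both, exact permutation test). Within NonTg, the 2 deep libraries had a mean DAM stage 2 score of 5.73 and the 3 shallow libraries 3.86; among shallow libraries alone the differences from NonTg were 4.27, 4.03 and 4.13 (adjusted p = 0.0689 for each, exact permutation test).

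**Figure D3:**
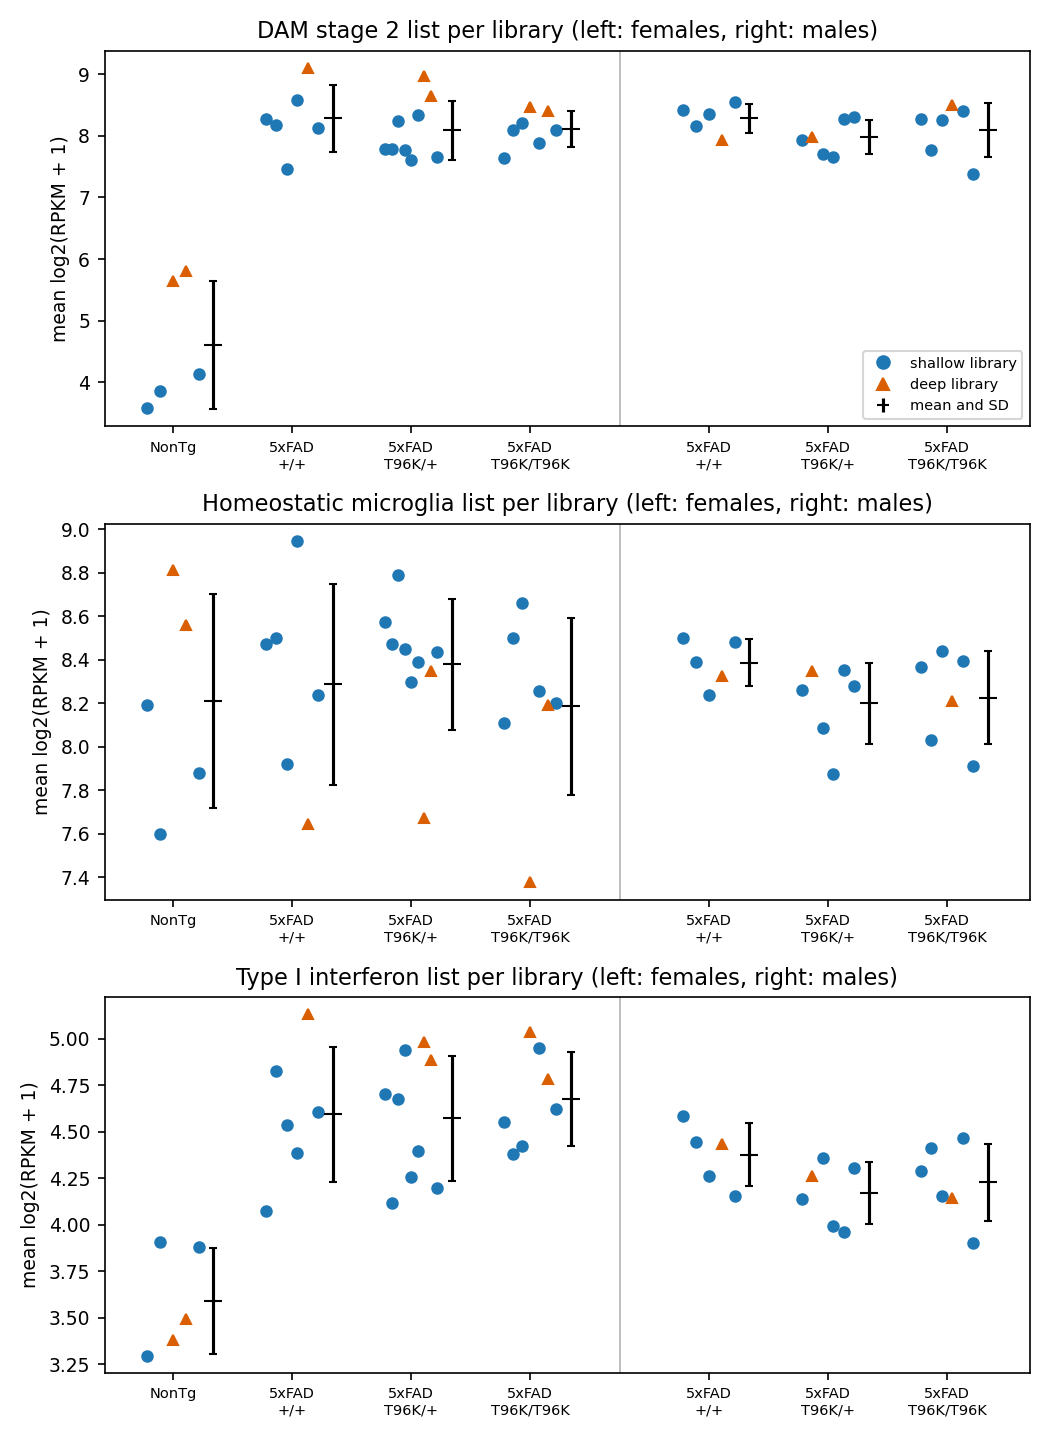
Mean log2(RPKM + 1) over the DAM stage 2, homeostatic and type I interferon lists in each library of the 7 groups, with the group mean and SD beside the points and deep libraries drawn as triangles. The 22 female 5xFAD libraries lie at or above 7.47 on the DAM stage 2 score and the 5 NonTg libraries below 6, while the T96K groups overlap Trem2+/+ in each sex.

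Whether T96K acted differently in females and males was tested as the difference of the effects over 13636 genes. For T96K/+, Apoe differed by 1.65 (SE 1.03), Spp1 by -0.59 (SE 0.80), Cst7 by 0.58 (SE 0.83) and Trem2 by 0.13 (SE 0.34), where a positive value is an effect higher in females. For T96K/T96K, Apoe differed by 1.65 (SE 1.05), Cst7 by 0.59 (SE 0.85) and Trem2 by 0.07 (SE 0.35). The genes with the smallest p, not called, were 1110012L19Rik (-0.57), Ppp1r26 (1.46), Gm11399 (1.72), Mppe1 (0.63) and Gm16146 (-1.43) for T96K/+, and Gm11399 (2.0), Mir338 (-1.75), Bccip (-0.56), Gm10973 (-2.24) and Psmg1 (-0.58) for T96K/T96K.

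Camera called 9, 7 and 7 of 30 lists for T96K/+, T96K/T96K and the trend. Oxidative phosphorylation genes differed by -0.30, -0.32 and -0.15, with Uqcrc2 at -0.26, -0.38 and -0.19 (adjusted p = 0.725, 0.88 and 0.887 with an estimated correlation). For T96K/+, lysosome genes differed by 0.24, homeostatic genes by 0.30, interferon genes by 0.20, with Stat2 at 0.67, and Alzheimer disease risk genes by 0.28, and beside these the erythroid list by -2.09 (4 of 5 genes adjusted over the list alone), with adjusted p = 0.725 with an estimated correlation for each. For T96K/T96K, oligodendrocyte genes differed by -0.76 (6 of 10 alone), with the myelin gene Mog at -1.71 (adjusted p = 0.241 with an estimated correlation). Limma and limma voom called 0 genes in each of the 3, beside 643, 760 and 863 at an unadjusted p under 0.05, and fry called 0 lists. Array weights called 39, 25 and 2 genes, the last being Gm11399 and Bccip. Without the library labelled female T96K/+ 22 the counts for T96K/+ and the trend were again 0.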

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

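The tests that weigh explanations in this part were chosen only after the result was seen; the list tests of the sex difference were chosen beforehand. A library was singled out where its gap to the nearest library of its group took up more of the group's range than Dixon's 95% critical value allows. In all, 161 groups of values over 23 quantities were tested and 19 stood out. For normally distributed values chance alone singles out about 1 in 20 groups. Several quantities, such as Apoe RPKM and depth, were skewed, so chance can single out more.

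The library labelled female T96K/+ 22 carried a male pattern, with Ddx3y at 14.4 RPKM against at most 0.0893 in the rest of its group. A swap with a male library of the series was argued against by 0 male libraries holding more Xist than Y-linked RNA, and a mixture of female and male RNA by its Xist, which was 0.967% of the median of the other females while its Y-linked sum was 92.6% of the male median. A wrong sex label, or RNA of a male mouse, goes with its Y-linked sum of 29.3 RPKM, inside the male range of 25.7 to 37.9. RNA of a male of the series sequenced a second time stays possible, as this library was not compared with single male libraries. Which mouse it came from stays open, and no biological explanation was tested.

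The 2 deep NonTg libraries, 28 and 30, held higher DAM stage 2 genes than the 3 shallow ones (score 5.73 against 3.86), though below the lowest female 5xFAD library at 7.47. Reads carried over from deep 5xFAD libraries would need 1 share for all genes, but the 11 genes needed shares from 1.3 to 29%, a ratio of 22.3, which argues against carry-over as the whole cause. A larger microglial share was argued against as the whole cause, since homeostatic genes were higher by a median of 0.918 log2 and DAM stage 2 genes by 1.907; a part of the difference could come from it. The deep female 5xFAD libraries, numbered 25 to 34 against 1 to 24 for the shallow ones, scored higher by 0.981, 0.925 and 0.451, but of the deep males the Trem2+/+ library was the lowest of its group (7.94, others 8.15 to 8.55), the T96K/+ library lay inside its group (7.98, others 7.66 to 8.31) and the T96K/T96K library was the highest (8.51). Whether the sequencing sets or the NonTg mice differed cannot be told apart, as each mouse was in 1 set only, and the males do not show 1 direction. Within the shallow female 5xFAD libraries, Cst7 of this list stood at 455.9 to 1213 RPKM in numbers 1 to 17. It stood at 1527 to 3336 in numbers 18 to 23, except 768.7 in library 22. Depth alone thus does not mark this step, and a step by library number was not modelled.

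All 44 ribosomal protein genes were higher in female 5xFAD Trem2+/+ than in NonTg microglia. Gene length bias was examined by removing a trend on the deposited length from each library. The difference went from 1.56 to 1.068 log2 for Trem2+/+, beside an SD of 0.339 in NonTg. It went from 1.34 to 0.96 for T96K/+ and from 1.54 to 1.10 for T96K/T96K (exact permutation p = 0.00216, 0.000999 and 0.00126 in turn). In Trem2+/+, other highly expressed genes were higher by a median of 0.915 up to 500 bases and 0.377 from 1000 to 2000 bases. The deposited lengths (ribosomal median 1466.5 bases) mostly merge all exons of a gene. A bias by these lengths was argued against as the whole cause, but a bias by transcript length was not excluded. RNA of other cells in the NonTg libraries could account for a part: with marker scores as covariates the median was 1.055 (SE 0.372) and the calls went from 44 to 3, but 0.84 (2 calls) for T96K/+ and 1.38 (40 calls) for T96K/T96K. For Trem2+/+ the median fell from 1.59 and its SE rose from 0.306. The adjustment was also stricter there, as it depends on how many genes pass, and 578 instead of 3438 genes were called in all. What each of these did to the ribosomal calls was not separated. What other cells contributed cannot be told apart from the genotype, as their markers moved with it. A change of ribosomal transcripts in 5xFAD microglia stays among the open explanations.

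Female T96K/+ library 26, one of the deep libraries, stood apart in its homeostatic score of 7.67 (nearest other 8.3), Trem2 at 1460 RPKM (1050), Spp1 at 1270 RPKM (647) and Gpnmb at 315 RPKM (148). Female T96K/T96K library 27, also deep, had a homeostatic score of 7.38 (nearest other 8.11), 147 RPKM of Xist (62.3) and an oligodendrocyte level of 4.34 log2 (3.12). Apoe reached 15200 RPKM in female Trem2+/+ library 19 (nearest other 5330) and 15700 RPKM in female T96K/T96K library 21 (5760). These values were part of a wider step by library number. Female 5xFAD libraries 1 to 17 held 504.8 to 2275 RPKM of Apoe and libraries 18 to 34 held 4991 to 15730, except 889.4 in library 22. NonTg libraries held 373.6 to 734.7. Libraries 18 to 23 were shallow, so the depth set does not mark this step, and its cause was not tested. Gpnmb reached 246 RPKM in female T96K/T96K library 3 (nearest other 138). Tmem119 was 327 RPKM in male Trem2+/+ library 2 (nearest other 414). Xist was 84.9 RPKM in NonTg library 10 (nearest other 31.8) and 0.374 RPKM in male T96K/+ library 3 (0.0813). Ddx3y was 0.0243 RPKM in female Trem2+/+ library 19 and 0.0181 RPKM in female T96K/T96K library 15, both near 0. Depth stood apart at 42.4 M reads in female Trem2+/+ library 25 (nearest other 12.4), 29.8 M reads in male T96K/+ library 22 (11.8) and 32.2 M reads in male T96K/T96K library 24 (12.4).

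By camera at the preset correlation, the T96K effect differed between the sexes for 9 lists (T96K/+), 7 lists (T96K/T96K) and 7 lists (trend); with an estimated correlation and by fry the difference held for 0 lists in each.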

How the results depend on the processing

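The settings added after seeing the data were the depth set, shallow libraries, the deep NonTg libraries, marker scores and voom; the others were planned. Unless named here, the total of genes called in a comparison stayed within 1.5 times the reported one. Counts by direction or list could move more. Lower genes in T96K/T96K against NonTg went from 737 to 1599 with array weights, 1379 with quantile normalization and 1282 in shallow libraries. They went to 484 with only the compared groups in the fit and 309 without NonTg 4, where 78.3% of the calls were higher. Lower genes in T96K/+ against NonTg went from 1032 to 458 without NonTg 4 and 501 without NonTg 24. These directional counts thus rested in part on single NonTg libraries. In shallow libraries higher genes in Trem2+/+ against NonTg went from 4 to 8 for TREM2 signalling and from 3 to 8 for Alzheimer disease risk. The 3 comparisons with NonTg called 578, 644 and 1055 genes with marker scores as covariates, and T96K/T96K against NonTg 3673 with array weights; the cause was not tested. They called 3813, 2919 and 2651 with the depth set as a covariate, 3916, 2941 and 3232 in shallow libraries, 3737, 2846 and 2246 without the 2 deep NonTg libraries, and 3762, 2747 and 2441 by voom. Array weights called 1 gene in female T96K/+ and 1 in T96K/T96K (Gm10973 in both, -1.67 and -1.92), 62 in male T96K/+, and 39, 25 and 2 for the sex difference; only the compared groups in the fit called 3 in male T96K/+; the cause was not tested.

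Leaving out 1 library at a time gave 2381 to 3648 genes for Trem2+/+ against NonTg, 1547 to 2806 for T96K/+ against NonTg (lowest without NonTg 4; 1549 without NonTg 24) and 1425 to 2713 for T96K/T96K against NonTg (lowest without NonTg 4). It gave 0 to 1 in female T96K/+ (Gm10973, -1.95, without Trem2+/+ 14; U6, -1.64, without Trem2+/+ 13), 0 to 1 in female T96K/T96K (Gm10973 without Trem2+/+ 14), 0 to 1 in male T96K/+ (AC161805.1, 3.28, without T96K/+ 22) and 0 to 1 in the male trend (Gm8974, -0.68, without T96K/T96K 5), and 0 throughout in the other T96K comparisons. DAM stage 2 score differences from NonTg ranged over 3.43 to 3.98, 3.23 to 3.78 and 3.25 to 3.81, with a largest adjusted p of 0.0357. The T96K differences of that score, never called, ranged over -0.36 to -0.04 and -0.34 to -0.01 for female T96K/+ and T96K/T96K and -0.39 to -0.24 and -0.27 to -0.04 for male ones. In shallow libraries alone the differences from NonTg were 4.27, 4.03 and 4.13 with adjusted p = 0.0689 for each (exact permutation test). Fewer libraries leave fewer permutations. The T96K differences there were -0.24 and -0.14 for female T96K/+ and T96K/T96K and -0.395 and -0.353 for male ones, again not called.

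List calls fell with an estimated correlation from 55 to 9 for 5xFAD against NonTg, from 33 to 0 for T96K in females, 65 to 0 in males and 23 to 0 for the sex difference; fry gave 52, 0, 0 and 0. Quantile normalization raised the sex difference to 36 lists. No scaling moved the median of all genes by over 0.1. In the comparisons with NonTg, no list median past camera changed sign under quantile normalization or median scaling. The gene calls of a list could still turn: for oxidative phosphorylation in Trem2+/+ they went from only higher to more lower than higher under quantile normalization. List medians of the T96K and sex comparisons were not computed under these settings. Of 207 named gene results that were called, 64 lost the call with marker scores and 1 changed sign, Kdr in Trem2+/+ against NonTg (0.043), a gene of the endothelial score itself. No paired analysis was possible because no 2 genotype groups of a sex share a library number.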

Other observations

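The tests on the male signature and the count at unadjusted p were chosen only after the result was seen.

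Levels of other cells' markers in the sorted libraries are given as values only, untested between the sexes since the tables were scaled separately. The neutrophil list mean was 6.55 ± 0.53 in male Trem2+/+ and 4.88 ± 0.995 in female Trem2+/+ 5xFAD libraries (SD, log2), with Ngp at 399 ± 155 and 98.2 ± 62.0 RPKM. The astrocyte list mean was 3.73 ± 0.79 and 3.02 ± 0.62, the endothelial mean 5.25 ± 0.72 and 5.21 ± 0.39, and the erythroid mean 2.47 ± 0.995 and 2.76 ± 0.80, in the same order. Among females the monocyte mean was 1.94 ± 0.83 in T96K/+, 3.06 ± 0.69 in Trem2+/+ and 3.27 ± 0.67 in T96K/T96K.

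Across genes, which are not independent replicates, the T96K/+ effect in females and males correlated at r = 0.23 and the T96K/T96K effect at 0.048. Of 100 labellings of the libraries, 15 and 78 gave a correlation as large in size.

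One hypothesis was that T96K lowers the female 5xFAD signature in males. A score of the 797 higher less the 489 lower genes was 1.75 ± 0.41 in male Trem2+/+ and 1.23 ± 0.56 in T96K/+ (SD, log2), a difference of -0.52 (95% interval -1.22 to 0.16; exact permutation p = 0.128, adjusted p = 0.384 over 3 comparisons), where the female 5xFAD difference was 2.98. T96K/T96K differed from Trem2+/+ by -0.21 (-1.03 to 0.56; exact permutation p = 0.584) and from T96K/+ by 0.32 (-0.51 to 1.10; exact permutation p = 0.394). The intervals hold 0, and the hypothesis stays open. Markers of other cells moved beside the score from male Trem2+/+ to T96K/+, endothelial from 5.25 to 5.75, astrocyte from 3.73 to 4.30 and mural from 4.0 to 4.59 (list means, log2), and were not separated from it.

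Splits of the libraries tested whether chance can be excluded; every count of splits includes the real one. For genes called against NonTg it was: 1 of 100 splits, the real one, reached 3438 for Trem2+/+, 2530 for T96K/+ and 2236 for T96K/T96K, and the highest other splits gave 2521, 1776 and 1560. Those splits still called many genes and also parted the libraries by endothelial level, by -0.99, -0.85 and 0.61 log2 against -1.21, -0.95 and -0.59 in the real ones. At an unadjusted p under 0.05, 1, 1 and 2 of 100 splits reached the real 5085, 4287 and 4305 genes, with highest others of 4536, 3862 and 4363, the last above the real count. For lists called against NonTg chance was not excluded, with 41, 13 and 11 of 100 splits reaching 17, 19 and 19 lists and highest others of 25, 22 and 25.

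For the T96K comparisons 100 of 100 splits reached the real count of 0 genes, which any split must, so the number says nothing about chance. The highest other splits called 12, 1, 2 and 0 genes in female T96K/+, T96K/T96K, their contrast and the trend, 2, 443, 2423 and 624 in the male ones, and 302, 82 and 2 for the sex difference. The splits calling 443, 2423, 624 and 302 genes were each the highest of their set, where the median of the other splits was 0. What sets them apart was not tested. The first and second of them parted the endothelial level by 0.69 and -1.29 log2. For lists, chance was not excluded in females (36, 91, 47 and 92 splits reaching 13, 5, 10 and 5 lists, highest others 20 in each) or for the sex difference (58, 71 and 80 splits reaching 9, 7 and 7; highest others 21, 24 and 20). In males 4 splits reached the 22 lists of T96K/+ (highest other 23), 22 the 17 lists of T96K/T96K (23), 52 the 10 lists of their contrast (22) and 16 the 16 lists of the trend (24). For genes at an unadjusted p under 0.05, 3 splits reached the 1703 of male T96K/+ (highest other 2154), 20 the 1193 of T96K/T96K, 81 the 342 of their contrast and 19 the 1052 of the trend. In females 44, 50, 42 and 39 splits reached the real counts, and for the sex difference 22, 33 and 24. As male T96K/+ was the lowest of 11 T96K comparisons, with no adjustment for that, chance was not excluded there either.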
